A study of Mus musculus with 2 samples.

How the data were processed

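H3K4me2 ChIP-seq was made from limbs of B6NCrl mouse embryos at day 11.5, with 2 biological replicates of pooled embryos of both sexes and a fragment size range of 300 to 500 bp, per the labels. The labels give each replicate its own embryo pool, 109 and 88 embryos, so the replicates differ by pool as well as by library preparation. The deposited data used here were 4 peak lists in narrowPeak format on mm10: 1 per replicate, 1 from the replicates pooled, and 1 of replicated peaks. Per the descriptions deposited with the samples, each list was made by the authors from filtered alignments with 2 control alignments. The peak caller, its version, its settings and the rule for keeping a peak as replicated are not given in the sources used here. Signal tracks and alignments were not analysed here. All 31850 replicated peaks stood in the pooled list with the same coordinates and values, making up 77.5% of it, and 27669 of them (86.9%) were touched by peaks of both replicates, 3784 by replicate 2 alone, 361 by replicate 1 alone and 36 by neither.

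The coordinates, summit position, score, signal value, −log10 p-value and −log10 q-value of each peak are the authors' own, as deposited, and apart from the score, which was not used here, they served to place peaks and to describe, rank or filter them, with signal also compared between the replicates. The score and the signal value are the authors' measures of a peak's strength on a linear scale, and their normalization is not given in the sources used here. The lowest −log10 p-value was between 2.02 and 2.15 in all lists, so they hold many weak peaks, and the replicated list holds peaks with a −log10 q-value as low as 0.285. The files give no read counts, so the depth of each library is unknown. Wilson intervals on shares of peaks or genes cover counting error only.

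Genes, transcripts and exons were taken from GENCODE M21, and sequence from the reference assembly of the same build, with 21938 protein-coding genes on 21 chromosomes. No peak lay past a chromosome end. The TSS was the annotated 5′ end of the gene, which for a few genes is an outlying transcript start. Per gene, the values computed were the presence of a peak within 1 kb of the TSS, the bases covered by peaks within 5 kb either side of the TSS (at most 10001 bp, called coverage or breadth), and the number of distal peaks, those with a midpoint over 2.5 kb from every protein-coding TSS, given to the gene with the nearest TSS. Distal peaks within 5 kb of a TSS also count in its coverage, so these measures are not wholly separate. The territory of a gene is the span in which its TSS is the nearest. CpG observed over expected was taken within 500 bp of the TSS. Peaks overlapped if they shared at least 1 bp. Overlaps were computed with bedtools 2.31.1, and all else with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9.

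The 14 gene lists were limb mesenchyme and patterning, limb ectoderm and apical ridge, cartilage condensation, migrating and early muscle, vascular endothelium, blood, neural crest and Schwann, brain, liver, heart, gut and pancreas, housekeeping, cell cycle, and olfactory receptors. All listed symbols matched the annotation, and Sox17 and Nkx2-2 stand on 2 lists each. Each list's value was compared with 10000 random lists of the same size, matched on decile of CpG observed over expected for promoter peaks and coverage and on decile of territory length for distal peaks. The permutation p-values are two-sided, and adjusted p-values are Benjamini-Hochberg values over the 14 lists for each measure. A raw p of 0.0002 is the smallest these lists can give. Genes and peaks are not replicates, so these p-values describe the 2 libraries and not limbs at large. Spans between named genes were compared with 1000 random autosomal windows of the same length and number of protein-coding TSSs, with adjustment over 14 spans and a smallest raw p of 0.002. In lists simulated from the measured means, 200 lists of 30 genes of each kind against 1000 random lists, p was under 0.05 in 3.5% of unchanged lists for promoter peaks and 2.0% for distal peaks, and in 100% of changed lists of either kind. The simulated changes were large, so the 100% does not bear on smaller ones. Genes were drawn independently, unlike real neighbours that share peaks, and coverage was not simulated.

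The groups, gene lists, spans, tests and alternatives were chosen before the data were examined, as was the rule for the genes named: in each list up to 4 genes with the most bases covered within 5 kb and up to 4 with none, the genes with a TSS in the 15 widest domains, the 10 distal peaks of highest signal, the 10 genes with most distal peaks, every Hox gene and listed span, and the 5 highest peaks found in 1 replicate only. The replicated list gave the main values. The alternatives were the pooled list, each replicate alone, a −log10 q-value of at least 5 or 10, other overlap rules, TSS windows of 500 bp and 2.5 kb, every annotated transcript start as a TSS, a 10 kb window for coverage, distal peaks over 5 kb from a TSS, the top 2000 distal peaks, no matching, and other merging distances. Restricting the replicated list to peaks touched by both replicates, and comparing strong peaks with all peaks of the other replicate, were chosen after seeing the data. Peaks on unplaced sequences were left out of all gene and region measures. With 1 group of 2 libraries, no test between groups and no test across samples could be made.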

Results

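Dimethylation of histone H3 at lysine 4 (H3K4me2), a chromatin mark found at promoters and enhancers that are active or open to activation, was profiled by chromatin immunoprecipitation and sequencing in mouse limb at embryonic day 11.5. At this stage the limb bud holds patterned mesenchyme, early cartilage condensations, an ectodermal cover with the apical ridge, and incoming muscle precursors, vessels and nerves. Limbs of the B6NCrl strain were pooled over embryos of both sexes, 109 embryos for replicate 1 and 88 for replicate 2. The 2 libraries form 1 group, so the comparisons are between the replicates and between genes and regions within this tissue. The data were 4 peak lists on mm10, and with no read counts in them the depth of each library is unknown. Replicate 1 had 56333 peaks over 34.4 Mb and replicate 2 had 50288 peaks over 43.5 Mb. The authors' replicated list, used for the main values, held 31850 peaks over 37.8 Mb, or 1.39% of the assembled chromosomes, with a median width of 946 bp.

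The first comparison asked how far the replicates held the same peaks. The strongest sites were found in both, and most peaks found in only 1 replicate were weak, narrow and distal. Of the replicate 1 peaks, 63.8% (95% Wilson interval 63.4 to 64.2) overlapped a replicate 2 peak by at least 1 bp, and 55.9% (55.5 to 56.4) of the replicate 2 peaks overlapped a replicate 1 peak. With peaks ranked by p-value and cut into 10 equal parts, all peaks in the 3 strongest parts were shared in each direction, against 26.4% of the weakest part in replicate 1 and 10.9% in replicate 2. Peaks found in replicate 1 alone had a median width of 199 bp and a median −log10 q of 1.98, and 92.0% lay over 2.5 kb from any protein-coding transcription start site (TSS). For peaks found in replicate 2 alone these values were 232 bp, 2.82 and 81.8%. At a −log10 q of at least 5 in both lists, 97.7% of the replicate 1 peaks and 73.0% of the replicate 2 peaks were shared.

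The 5 highest peaks of replicate 1 with no counterpart lay nearest Btg2, Rnd3, Sfswap, Ckap2l and Wwc1, with signal values from 7.77 at Btg2 to 6.15 at Wwc1. Those of replicate 2 were nearest Crebzf, Ggta1, C1galt1c1, Ttll12 and Gpc3, with signal values from 12.4 to 12.1, and those at Ggta1, C1galt1c1, Ttll12 and Gpc3 were within 1 kb of the TSS. Peaks were narrower in replicate 1: of the replicate 2 peaks that it touched, 25.1% held 2 or more replicate 1 peaks, against 3.15% the other way. Over the 19535 peaks that paired uniquely between the replicates, log2 signal values had a Pearson r of 0.906 and a Spearman rho of 0.913, across peaks, which are not independent replicates. Signal was lower in replicate 1 at 89.8% of them, with a median log2 ratio of −0.71, and of −0.83 within 1 kb of a TSS and −0.56 over 2.5 kb away. Of the peaks found in replicate 2 alone, 3419 had a −log10 q of at least 5.

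**Figure D1:**
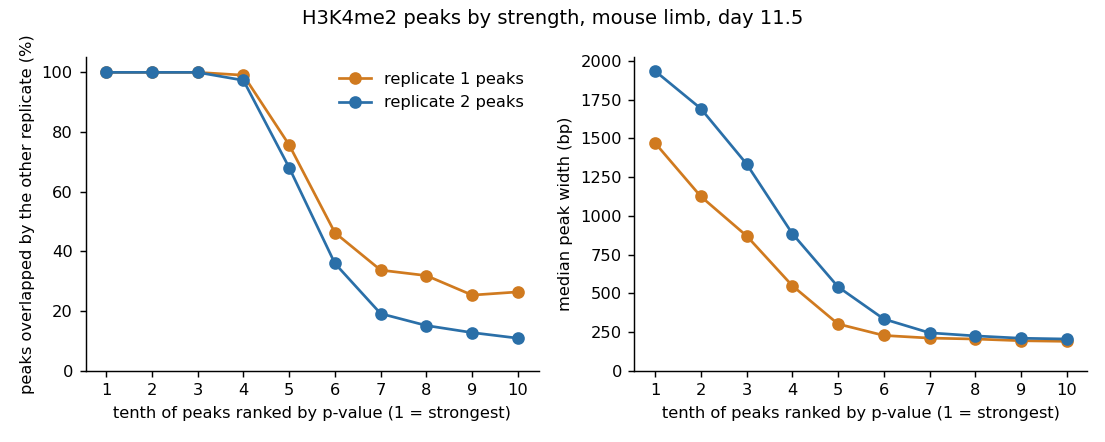
Share of each replicate's peaks overlapped by the other replicate (left, %) and median peak width (right, bp) for 10 equal parts of the p-value ranking, from the strongest (1) to the weakest (10), with replicate 1 in orange and replicate 2 in blue. All peaks of the 3 strongest parts were shared, and in the weakest part 26.4% of replicate 1 and 10.9% of replicate 2 peaks were.

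The mark lay at promoters far more often than their share of the genome. By midpoint, 43.0% (95% Wilson interval 42.5 to 43.6) of the replicated peaks were within 1 kb of a protein-coding TSS, a class that makes up 1.56% of the genome, for a 27.6-fold excess. A further 9.24% were in exons, 24.9% in introns and 22.8% between genes, where 3.26%, 35.1% and 60.1% of the genome lies. Promoter peaks had a median width of 1374 bp and a median signal of 17.1. The 14939 peaks over 2.5 kb from a TSS, 46.9% of the list, had a median width of 585 bp and a median signal of 5.50. Of these distal peaks 9529 (63.8%) were also over 2.5 kb from every annotated transcript start of any gene type. With every transcript start counted as a TSS, the exon share was 4.18% and the promoter share 55.2%.

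Promoters of most protein-coding genes carried the mark, and CpG content separated those that did from those that did not. A peak overlapped the TSS ± 1 kb of 13761 of 21938 genes (62.7%, 95% Wilson interval 62.1 to 63.4). The share was 1.69% in the lowest decile of CpG observed over expected, 37.7% in the fourth, 80.4% in the fifth and 99.3% in the highest. X-linked promoters were marked less often than CpG content gives: 462 of 948 X-linked genes (48.7%, 45.6 to 51.9) had a promoter peak, against a mean of 54.0% over 10000 lists of autosomal genes matched on CpG decile, with 52.1 to 56.0% as their central 95% range. The two-sided permutation p was 0.0002, the smallest that 10000 lists can give, and it took that value under all 8 alternatives.

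The next comparisons asked which genes carried broad or numerous H3K4me2 sites, over 14 gene lists. Limb mesenchyme and patterning genes had the broadest coverage. Their median coverage within 5 kb of the TSS was 6538 bp, against 1924 bp for lists matched on CpG decile (adjusted permutation p = 0.0014, Benjamini-Hochberg over the 14 lists), and it was 5382 bp in replicate 1 and 6517 bp in replicate 2. Of the 57 genes, 39 had over 5 kb covered, a breadth that 2.32% of all protein-coding genes reached. Lmx1b, which sets dorsal identity in the limb, was covered over all 10001 bp of the window in the replicated list and in each replicate. Hoxd11, Hoxa10 and Hoxd10, which pattern the limb along its length, had 10001, 9961 and 9948 bp, near the limit of the window. Fgf10, the mesenchymal signal for limb outgrowth, had 0 bp at the 5′ end of its annotation and carried a peak at another of its annotated starts.

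Cartilage genes had a median of 2860 bp against 1658 bp in matched lists (adjusted permutation p = 0.0014), with 2096 bp in replicate 1 and 3254 bp in replicate 2. The broadest were Foxc1 at 6860 bp, Sox9, the main regulator of chondrocyte fate, at 6774 bp, Sox6 at 6416 bp and Col2a1, the chief collagen of cartilage, at 5814 bp, whereas Matn1 had 0 bp in the replicated list (190 and 259 bp in replicates 1 and 2), as did the annotated 5′ end of Col9a1, which had a peak at another start. Housekeeping genes had 2860 bp against 2010 bp (adjusted permutation p = 0.0028), led by Tubb5 at 6282 bp, Rpl13a at 5422 bp, Rps18 at 5327 bp and Polr2a at 4919 bp. Cell cycle genes had 2794 bp against 2206 bp (adjusted permutation p = 0.028), led by Rrm2 at 4285 bp and Mcm2 at 4084 bp, ahead of Plk1 at 3728 bp and Mki67 at 3727 bp (2348 bp in replicate 1). The cell cycle call ended with a 10 kb window (adjusted permutation p = 0.0637, range over alternatives 0.00056 to 0.0637).

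The remaining lists did not pass in breadth against CpG-matched genes, with adjusted p from 0.289 to 1. The labels name limb and no sorted cell type, and the share of each cell type is unknown. A gene without a peak could still carry the mark in a minority of the cells. The medians of the blood, liver and olfactory receptor lists were 0 bp, so a deficit in them could not be seen. Ectoderm and apical ridge genes had a median of 1436 bp against 1450 bp, and among them Fgf9 (5496 bp), Tfap2c (4274 bp), Sp8 (3753 bp, and 2498 bp in replicate 1) and Esrp2 (3250 bp) were the broadest while Fgf4, Trp63, Krt5 and Krt14, the latter pair keratins of basal epidermis, had 0 bp in the replicated list, with a peak at another start of Fgf4. Muscle genes had 992 bp against 1264 bp, with 601 bp in replicate 1 and 1368 bp in replicate 2. The broadest of them were Six1, Lbx1, Six4 and Eya2, at 4782, 4030, 3999 and 2351 bp, with Lbx1 at 2670 and 4992 bp and Eya2 at 1247 and 2550 bp in replicates 1 and 2. Myog, Ttn and Myh3 had 0 bp in the replicated list (Myog 601 bp in replicate 1, Myh3 245 and 251 bp in replicates 1 and 2), as did the annotated 5′ end of Mef2c, which had a peak at another start. These genes were named by their coverage, and early and late muscle genes were not compared. Endothelial genes had 1470 bp against 1022 bp, and in replicate 1 alone 620 bp against 824 bp, with Fli1 at 8286 bp ahead of Sox18 at 2898 bp, Ramp2 at 2473 bp and Erg at 2308 bp, and none at Pecam1, Tek, Tie1 and Emcn. Neural crest and Schwann genes had 1755 bp against 1266 bp. In that list Ngfr had 3597 bp, Erbb3 3490 bp, Tfap2a 3471 bp and Tfap2b 2578 bp (1114 and 3313 bp in replicates 1 and 2). Plp1, Dct, Cdh19 and Fabp7 had 0 bp in the replicated list (Dct 460 bp in replicate 2).

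Among the lists of other organs, brain genes had a median of 1614 bp against 1824 bp, heart genes 584 bp against 396 bp (956 bp in replicate 1 alone), gut and pancreas genes 543 bp against 1130 bp, and liver and blood genes 0 bp against 23.9 and 2.45 bp. A gene on the list of another organ can also be used in the limb, which was not examined for any of these lists. Regulators on the brain list were among the marked ones, Dlx2 at 4033 bp, Emx1 at 2903 bp and Ascl1 at 2809 bp, with the neurofilament gene Nefm at 3230 bp. Neurod4 and the glutamate transporter gene Slc17a6 had 0 bp, as did the annotated 5′ ends of Gad1 and Pax6, both of which had a peak at another start. In the heart list Gata6 (5974 bp), Hand1 (5123 bp, and 3395 and 6014 bp in replicates 1 and 2), Myl3 (4528 bp) and Tnni3 (2860 bp, and 1481 and 3079 bp) were broadest. Tnni3 had no peak within 1 kb of its 5′ end, only at another start. In the replicated list Myh6, Myh7, Myl2 and the 5′ end of Gata4 had none, with a peak at another start of Gata4. Myh6 had 191 bp in replicate 1 and Myh7 190 bp in replicate 2. Isl1 had 5652 bp (3296 and 5940 bp in replicates 1 and 2), Onecut2 2918 bp, Nkx6-1 2852 bp and Sox17 1929 bp (1172 and 1923 bp) in the gut and pancreas list. In it Pdx1, Ins1, Ins2 and Gcg had none in the replicated list, although Pdx1 had 191 and 385 bp in replicates 1 and 2 and Ins2 and Gcg 190 bp each in replicate 1. Foxa3 (2429 bp), Apoh (2260 bp), Foxa1 (1948 bp) and Apoa2 (1806 bp) were the broadest liver genes, with none at Alb, Afp, Apob and Ttr. Apoa2 had no peak within 1 kb of any of its annotated starts, so its covered bases lay further out. Lyl1 (2878 bp), Epor (2510 bp), Tal1 (2079 bp) and Klf1 (1892 bp), regulators and a receptor of the blood lineages, were broadest in the blood list, in which Gata1, Gfi1b, Hba-a1 and Hba-a2 had none in the replicated list. Lyl1 was first in replicate 2, at 3770 bp, but in replicate 1, at 1706 bp, it fell behind Epor, Tal1 and Klf1 at 1997, 1790 and 1754 bp.

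**Figure D2:**
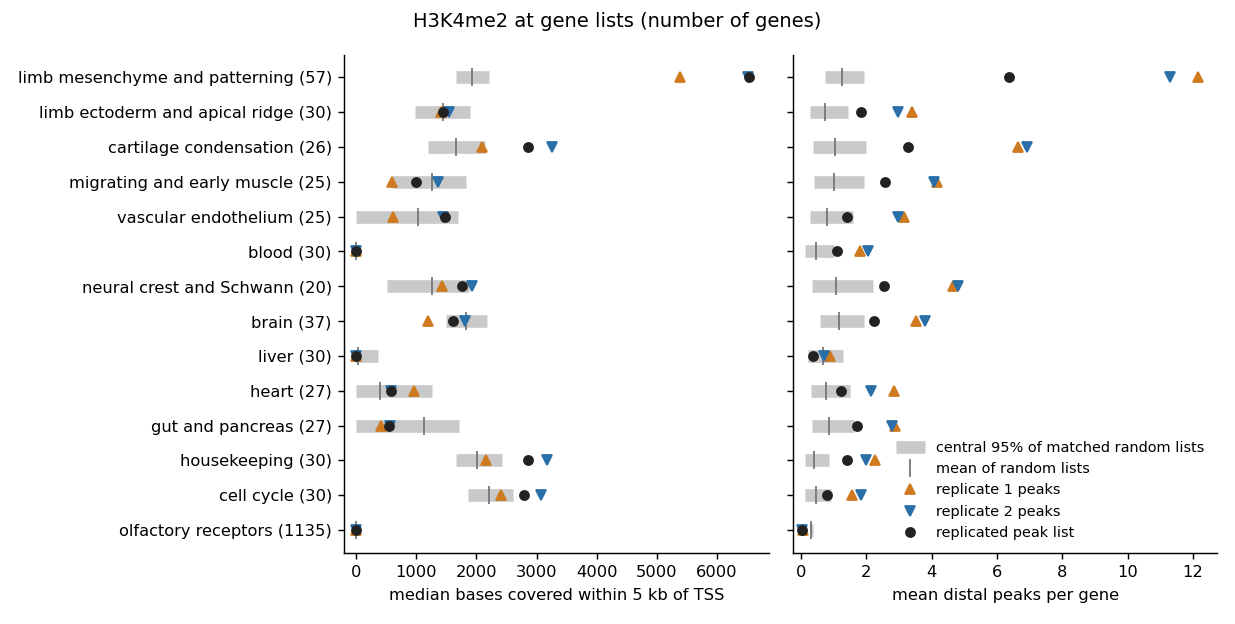
Median number of bases covered within 5 kb of the TSS (left) and mean number of distal peaks per gene (right) for each gene list, with the number of genes in brackets. Black circles are the replicated list, orange and blue triangles replicates 1 and 2, grey bars the central 95% range of 10000 matched random lists for the replicated list and ticks their mean. The limb mesenchyme list lies at 6538 bp and 6.37 distal peaks per gene, outside both grey bars.

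As shares of promoters with a peak, limb mesenchyme passed in the main setting, by a margin that several alternatives removed. Of its 57 genes, 56 had a promoter peak (98.2% against 89.6% in matched lists). For this list the adjusted p was 0.0392, which rose to 0.091 at a −log10 q of at least 5, 0.0819 with a 500 bp window, 0.0686 with a 2.5 kb window and 0.0546 without replicate 1 (range over alternatives 0.00056 to 0.091). Olfactory receptor genes, a low reference taken to be silent in the limb, had a promoter peak at 1 of 1135 genes, Olfr658, against 5.27% in CpG-matched lists (adjusted permutation p = 0.0028), and only Olfr94, Olfr95 and Olfr658 had any base covered, at 1223, 614 and 249 bp. In replicate 1 alone 6 of these genes had a promoter peak and 20 any base covered, and in replicate 2 alone 3 and 7. Promoter peaks were found at 22 of 30 ectoderm genes, 23 of 26 cartilage genes, 15 of 25 muscle genes, 15 of 25 endothelial genes, 7 of 30 blood genes, 14 of 20 neural crest genes, 30 of 37 brain genes, 5 of 30 liver genes, 12 of 27 heart genes, 12 of 27 gut and pancreas genes, 29 of 30 housekeeping genes and all 30 cell cycle genes. Against matched lists the liver share was 16.7% to 30.2% and the gut and pancreas share 44.4% to 56.3% (both adjusted permutation p = 0.108), the cartilage share was 88.5% to 74.4% (adjusted permutation p = 0.102, range over alternatives 0.0132 to 0.155, with 4 of 9 passing), and the other lists had an adjusted p of 0.346 or more.

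Distal peaks, which include enhancers, were also most numerous around limb genes. Limb mesenchyme genes had a mean of 6.37 distal peaks with their TSS as the nearest, against 1.27 in lists matched on territory length (adjusted permutation p = 0.00093), and 52 of the 57 genes had at least 1. Cartilage genes had 3.27 against 1.04 (adjusted permutation p = 0.00093), with 19 peaks at Sox9 and 12 at Foxc1, and 6.65 against 2.44 in replicate 1 alone and 6.92 against 2.18 in replicate 2 alone. Muscle genes had 2.56 (adjusted permutation p = 0.00952), neural crest genes 2.55 (0.0294), brain genes 2.24 (0.0248), ectoderm genes 1.83 (0.0121) and housekeeping genes 1.40 (0.0028), against matched means of 1.02, 1.06, 1.17, 0.745 and 0.415. Olfactory receptor genes had fewer, 0.0256 against 0.318 (adjusted permutation p = 0.00093). Endothelial (1.40), blood (1.10), liver (0.367), heart (1.22), gut and pancreas (1.70) and cell cycle genes (0.80) did not pass, with adjusted p from 0.052 to 0.262. In the longer lists of the single replicates the limb mean was 12.1 for replicate 1 and 11.3 for replicate 2. The brain, muscle and neural crest calls each ended with either replicate alone, at adjusted p of 0.0938 and 0.199, 0.0595 and 0.070, and 0.0595 and 0.0796, and the ectoderm call ended with replicate 2 alone, at 0.0595.

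With the 5000 distal peaks of highest signal, the limb list kept the largest excess, 1.63 per gene against 0.366 (adjusted permutation p = 0.0014), and the olfactory receptor list remained low, at 0.00793 against 0.134 (0.0014). Muscle genes had 0.80 against 0.315 (0.049, range over alternatives 0.028 to 0.487, kept in 1 of 3) and housekeeping genes 0.467 against 0.157 (0.0392, range 0.028 to 0.369, kept in 2 of 3). No other list passed in the main setting: heart 0.63 (0.056), brain 0.676 (0.0789), ectoderm 0.50 (0.138), cartilage 0.615 (0.176), neural crest 0.60 (0.255, range over alternatives 0.0358 to 0.773, passing without replicate 2), blood 0.30 (0.307), cell cycle 0.233 (0.706), endothelium 0.32 (0.753), liver 0.167 (0.833) and gut and pancreas 0.259 (1).

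The single genes with the most distal peaks in the replicated list were Nr2f2, a nuclear receptor, and Zfp608, with 27 each. In the longer lists of replicates 1 and 2 Zfp608 had 48 and 65, Zfhx3 48 and 43, Lmx1b 46 and 34 and Nr2f2 38 and 40, so that the order changed. Lmx1b had 26, Gins2 and Tbx3 24 each, Bcor, Smad7 and Zfp516 23 each, and Gse1 and Zfhx3 22 each. Relative to territory they were densest at Lmx1b (12.4 per 100 kb), Gins2 (11.5) and Gse1 (10.7), the latter pair neighbours on chromosome 8, and lower at Nr2f2 (2.08) and Zfp608 (2.13). The annotated bodies of Gse1 (120228456 to 120581390) and Gins2 (120578633 to 120589304) overlap. Peaks given to Gins2 by nearest TSS can thus lie inside Gse1, and the pair may be a single locus rich in distal peaks. The distal peaks of highest signal were mostly inside genes or near noncoding starts. The highest, at chromosome 17:23699079 to 23700422 with a signal of 49.5, lay between genes 15.7 kb from Cldn9. That at chromosome 6:31215829 to 31218994 (49.2) had Mkln1 as its nearest protein-coding gene, 181 kb away, and the noncoding gene 2210408F21Rik at 2.94 kb. The other 8 lay within Plxnb2 (47.3), Camta1 (45.8, nearest TSS that of Gm13090), Kcnma1 (45.2), Srcin1 (45.1), Phactr1 (44.7), Scd2 (44.0), Ank2 (43.8) and N4bp2l1 (43.8), and those in Kcnma1 and Ank2 were under 1 kb from a noncoding gene's start. The Scd2 peak, 5172 bp wide with its midpoint 2.96 kb from the TSS, reaches within 1 kb of that TSS and is distal by its midpoint alone. Each of the 10 was overlapped by peaks of both replicates.

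The widest stretches of the mark held Hox genes and other limb regulators. With peaks up to 1 kb apart merged there were 24543 domains, 54 of them 10 kb or wider, and 40367 in replicate 1 alone and 35601 in replicate 2 alone. The widest, 68.6 kb at chromosome 6:52200064 to 52268647, held the TSSs of Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13 and of Gm28308, and peaks of replicate 1 covered 89.9% and of replicate 2 96.0% of it. A 39.1 kb domain at chromosome 15:102945329 to 102984382 held Hoxc5, Hoxc9, Hoxc10 and Hoxc11, and a 36.2 kb domain at chromosome 2:74666158 to 74702406 held Hoxd9 to Hoxd13. Next were Lmx1b (21.3 kb), Tbx5, the forelimb T-box gene (17.1 kb), Bahcc1 (16.4 kb), Shox2 with Rsrc1 (16.4 kb), a domain within Tbx15 away from its annotated 5′ end (16.2 kb), Tbx3 (16.2 kb), Tbx2 (16.1 kb), Zfhx4 (15.3 kb), Zic2 (14.5 kb), Lhx9 (14.3 kb), Wnt5a (14.1 kb) and Pitx1, the hindlimb determinant (14.1 kb). Domains of 10 kb or more held the annotated 5′ ends of 26 of the 57 limb mesenchyme genes, against 67 of 21938 protein-coding genes (0.305%), 1 cartilage gene (Sox6) and no annotated 5′ end from the other 11 lists examined, which left out the olfactory receptors. The 67 include the 26, and these counts were not matched on CpG content. Among the 26, Hoxa9, Hoxa10, Hoxa11 and Hoxa13 shared a domain, as did Hoxd9 to Hoxd13, so the genes are not separate cases. Tfap2a, on the neural crest list, had an 11.1 kb domain over other starts of its own. With only touching peaks merged the widest domain was 13.8 kb and 10 of the 30 genes in the 15 widest domains stayed among them. The number of domains of 10 kb or more was 14 in that setting and 165 with peaks up to 3 kb apart merged.

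Within the Hox clusters, coverage differed by cluster and by member. Peaks covered 76.0% of HoxA, 57.4% of HoxD, 51.6% of HoxC and 23.6% of HoxB. In each cluster replicate 1 had the lower coverage, 66.2%, 51.5%, 43.6% and 16.6% in that order, against 78.7%, 58.2%, 59.1% and 27.7% in replicate 2. The HoxB span was the longest, at 174 kb. It includes the wide gap between the TSSs of Hoxb13 (96194316) and Hoxb9 (96271457), so its share is not directly comparable with the others. Members 9 to 13 had median coverage within 5 kb of 9867 bp in HoxA, 9887 bp in HoxD, 9146 bp in HoxC and 1568 bp in HoxB. In HoxA, Hoxa7 had 10001 bp and Hoxa5, Hoxa6, Hoxa9, Hoxa11 and Hoxa13 had 8879, 9926, 9795, 9939 and 9457 bp. The annotated start of Hoxa3 is an outlying one between those of Hoxa6 and Hoxa7, and the 9750 bp around it are not those of its main promoter. The 3′ members Hoxa1, Hoxa2 and Hoxa4 had 5229, 6344 and 2459 bp (3620 and 6862 bp for Hoxa2 in replicates 1 and 2). In HoxD, Hoxd12 had 9887, Hoxd9 8796 and Hoxd13, which acts in the digits, 7239 bp. Hoxd8 had 7355 bp and Hoxd1 1711 bp. The annotated starts of Hoxd3 and Hoxd4 are outlying ones that nearly coincide, so their 7755 and 7753 bp are a single window.

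In HoxC, Hoxc9, Hoxc10 and Hoxc11 had 9146, 9526 and 9159 bp, whereas the next members toward the 5′ end, Hoxc12 and Hoxc13, had 2316 and 1631 bp (759 and 2177 bp for Hoxc13 in replicates 1 and 2). The annotated start of Hoxc5 lies beside that of Hoxc10 and had 9527 bp, Hoxc6 had 6177 bp, Hoxc4 2579 bp (1642 and 4276 bp) and Hoxc8 2233 bp (1115 and 3525 bp). In HoxB, Hoxb2 to Hoxb8 ranged from 3130 bp at Hoxb3, the only Hox gene with no peak at its annotated 5′ end, through 4108 bp at Hoxb6, 5065 bp at Hoxb4, 5168 bp at Hoxb5 and 5371 bp at Hoxb2 to 5739 bp at Hoxb7 and 5749 bp at Hoxb8. Replicates 1 and 2 had 2445 and 5157 bp at Hoxb6, 3103 and 6229 bp at Hoxb5 and 3018 and 4190 bp at Hoxb3, so that in replicate 1 Hoxb6 lay below Hoxb3. Hoxb9, Hoxb13 and Hoxb1 had 2330, 806 and 341 bp (190 and 522 bp for Hoxb1).

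**Figure D3:**
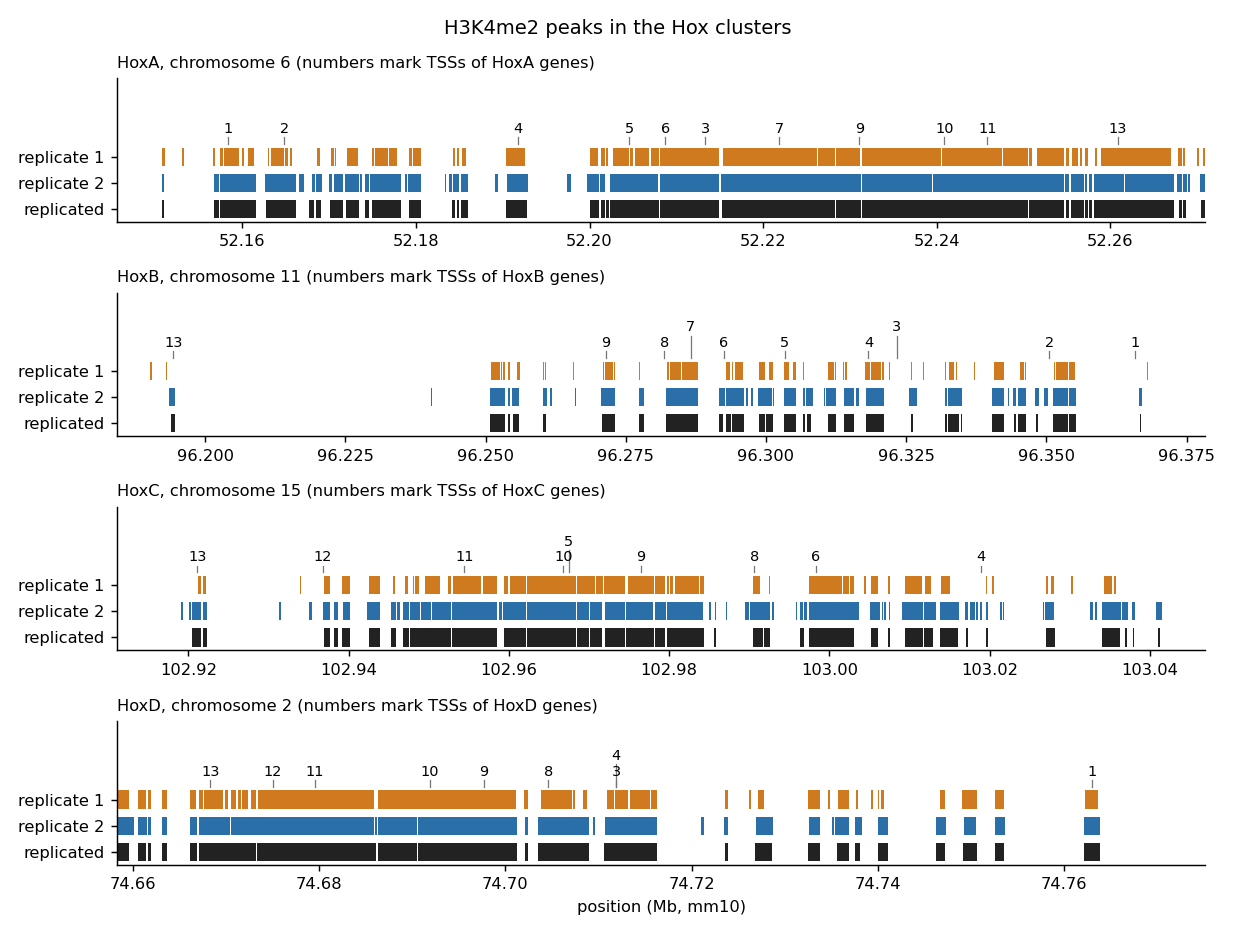
Peaks of replicate 1 (orange), replicate 2 (blue) and the replicated list (black) in the 4 Hox clusters, with position in Mb on mm10 and numbers marking the TSSs of the cluster's genes. Coverage is near continuous from Hoxa5 to Hoxa13, from Hoxc11 to Hoxc9 and from Hoxd13 to Hoxd9. It is lower over HoxB, of which 23.6% was covered and whose span includes the wide gap between Hoxb13 and Hoxb9.

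Spans that hold long-range enhancers of limb genes were compared with random windows of the same length and TSS number. The gene desert between Mtx2 and Hnrnpa3, on the 3′ side of HoxD, held 20 distal peaks over 12342 bp, against a window mean of 705 bp (99.7th percentile, adjusted permutation p = 0.14). Its highest peak, at chromosome 2:75137094 to 75138367 with a signal of 19.1, was found in both replicates. The desert between Evx2 and Atp5g3, on the 5′ side, held 14 peaks over 6151 bp (91.7th percentile), with a highest signal of 7.54. In replicates 1 and 2 alone, peaks covered 5532 and 11301 bp of this desert and 11568 and 19887 bp of that between Mtx2 and Hnrnpa3. Between Pitx1 and Neurog1 there were 17 peaks over 12809 bp (98.4th percentile), between Lbx1 and Fgf8 15 peaks over 11838 bp (97.0th percentile), and between Evx1 and Tril 18 peaks over 8786 bp (83.5th percentile), the last with 49 peaks over 12748 bp in replicate 1 alone and 51 over 16750 bp in replicate 2 alone. The gene body of Fmn1, which holds enhancers of Grem1, had 5 peaks over 2961 bp, that of Gli3 3 over 2740 bp, the span from Kcnj2 to Sox9 6 over 2114 bp and that from Tbx5 to Rbm19 3 over 1387 bp. In replicates 1 and 2 alone the last 3 of these had 2890 and 1268 bp, 3927 and 3501 bp, and 1629 and 2786 bp covered. Gli3 thus fell below its window mean of 1823 bp in replicate 2 alone.

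The gene body of Lmbr1, whose intron 5 holds the limb enhancer of Shh, had no distal peak in the replicated list, and its only peak lay at its promoter. No peak lay in intron 5 in the lists of either replicate. Of the spans chosen for other tissues, Sox2 to Atp11b held 9 peaks over 5611 bp (98.6th percentile), Foxg1 to Prkd1 3 over 2331 bp (91.7th percentile) and Isl1 to Pelo 5 over 3324 bp (71.0th percentile), and the 3.66 kb between Pax6 and Elp4, too short to hold the Pax6 enhancers inside Elp4, held none. All percentiles given here were lower against windows matched on length alone. They were then 93.2 for Mtx2 to Hnrnpa3, 79.2 for Evx2 to Atp5g3, 97.6 for Pitx1 to Neurog1 and 96.3 for Lbx1 to Fgf8. For Evx1 to Tril, Sox2 to Atp11b, Foxg1 to Prkd1 and Isl1 to Pelo they were 66.3, 64.7, 50.8 and 47.9. No span passed in the two-sided permutation test after adjustment over the 14 spans, with adjusted p from 0.14 to 1.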

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

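The count of these peaks was chosen after the files were seen. Signal was found outside the assembled chromosomes, which no comparison in the report used. On unplaced sequences the replicate 1 list held 16 peaks, the replicate 2 list 12, the pooled list 14 and the replicated list 10. The highest signal among the 10 replicated ones was 8.54, and no peak lay on the mitochondrial genome in any list.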

How the results depend on the processing

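No paired analysis was possible because the samples form 1 group. The overlap and signal comparisons use both replicates, so leaving one out gives no value there. The restriction to replicated peaks touched by both replicates, and the comparison of strong peaks with all peaks of the other replicate, were chosen after the data were seen. The X-linked deficit kept its direction and side of the threshold under all 8 alternatives, as did the coverage and distal excess of limb mesenchyme and of cartilage genes under all 7. Of 98 coverage, 98 distal, 126 promoter, 42 top distal and 84 span alternatives, 88, 85, 92, 37 and 80 kept direction and call. Except where the setting itself changes the number of peaks or the size of a window, the cause was not tested.

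The share of replicate 1 peaks found in replicate 2 was 36.6% with 50% reciprocal overlap, 97.7% at a −log10 q of at least 5, 99.8% at 10, 96.3% with equal numbers of peaks and 98.7% for strong peaks against all. The share for replicate 2 was 42.1% with 50% of the peak covered, 41.0% reciprocal, 73.0% at 5, 74.7% at 10, 81.4% with equal numbers and 87.8% against all. Pearson r was 0.852 at a −log10 q of at least 5, 0.879 near TSSs and 0.874 away from them, and the median log2 ratio −0.80, −0.83 and −0.56. The promoter share of peaks was 35.0% in the pooled list, 50.5% at a −log10 q of at least 5, 47.7% for peaks touched by both, 53.1% with a 2.5 kb window and 55.2% with every start. Exon shares were 6.59% and 4.18% in the last 2 of these settings. The intron shares were 30.1%, 20.1%, 22.2%, 19% and 17.8% in the same order of 5, and the intergenic shares 25.6%, 20.2%, 20.8% and 21.3% in the first 4. With a replicate left out, promoter, exon, intron and intergenic shares were 28.9 to 30.3%, 8.66 to 9.03%, 33.6 to 33.8% and 27.4 to 28.3%. The share of promoters with a peak was 61.8% at a −log10 q of at least 5, 61.7%, 64.4% and 66.3% with 500 bp, 2.5 kb and every start, and 62.8 to 64.1% with a replicate left out.

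Among list promoter shares, the limb call ended at 96.5% with a −log10 q of at least 5 or a 500 bp window and at 98.2% with a 2.5 kb window. The cartilage share passed at 92.3% in the pooled list, without replicate 1, also at 92.3%, and at 88.5% for peaks touched by both and with no matching. Liver passed at 13.3% for peaks touched by both and at 16.7% with no matching, and gut and pancreas at 40.7% at a −log10 q of at least 5 and for peaks touched by both and at 44.4% with every start. Housekeeping (96.7%) and cell cycle (100%) passed with no matching. The direction turned, without passing unless stated, for ectoderm at 66.7% with 500 bp, muscle at 68.0% in the pooled list, with 2.5 kb and with every start, endothelium at 60% with no matching, blood at 23.3% with 2.5 kb and, passing, with no matching and at 26.7% with every start, neural crest at 60% for peaks touched by both and with 500 bp, brain at 83.8% in the pooled list and with 2.5 kb, 89.2% with every start and, passing, 81.1% with no matching, and heart at 51.9% with 2.5 kb and 55.6% with every start. Without replicate 1 the direction also turned for muscle and brain, and without replicate 2 for neural crest. With a replicate left out the shares were 98.2% both times for limb mesenchyme, 88.5 to 92.3% for cartilage, 56.0 to 68.0% for muscle, 60 to 80% for neural crest and 78.4 to 86.5% for brain.

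In coverage, the cell cycle call ended at 3007 bp with a 10 kb window, and olfactory receptors passed at 0 bp with no matching. The direction turned for ectoderm at 1580 bp in the pooled list, 1706 bp with 10 kb and 1436 bp with no matching, for brain at 1614 bp with no matching, and for heart at 584 bp with 10 kb and with no matching. With a replicate left out it turned for ectoderm (1409 to 1547 bp) and endothelium (620 to 1440 bp), each without replicate 2. In distal peaks, muscle (2.92), neural crest (3.45) and brain (3.14) ended in the pooled list and housekeeping (1.40) with no matching, while gut and pancreas passed at 1.33 with a −log10 q of at least 5 and at 1.70 with no matching. With a replicate left out the means were 2.97 to 3.4 for ectoderm, 4.08 to 4.16 for muscle, 4.65 to 4.8 for neural crest and 3.51 to 3.78 for brain, 6.65 to 6.92 for cartilage and 2 to 2.27 for housekeeping, and in every list the mean and its matched mean rose together. Among top distal peaks, muscle (0.24) and housekeeping (0.167) ended with the top 2000, muscle ended without replicate 1 and neural crest passed without replicate 2, and with a replicate left out the means were 0.76 to 0.88 for muscle, 0.40 to 0.95 for neural crest and 0.222 to 0.333 for gut and pancreas. Domains of 10 kb or more numbered 14 with touching peaks, the widest of 13.8 kb, and 165 with 3 kb merging. HoxA was covered over 66.2 to 78.7% and HoxD over 51.5 to 58.2% with a replicate left out. Spans matched on length alone fell below the window mean for Kcnj2 to Sox9 (2114 bp), Foxg1 to Prkd1 (2331 bp) and Isl1 to Pelo (3324 bp), and Gli3 did so without replicate 1 (1268 to 2890 bp with a replicate left out). Left out in turn, the replicates gave 5532 to 11301 bp for Evx2 to Atp5g3, 11568 to 19887 bp for Mtx2 to Hnrnpa3, 12748 to 16750 bp for Evx1 to Tril, 3501 to 3927 bp for Kcnj2 to Sox9 and 1629 to 2786 bp for Tbx5 to Rbm19.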

Other observations

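The groupings in this part and both tests on the replicates were chosen only after related results had been seen, and the tests on limb coverage and distal peaks were set before their own results but after the patterns they bear on. Of the 67 genes in domains of 10 kb or more, 40 were on no list, among them the transcription factor genes Prdm16 (13.9 kb), Tshz1 (13.6 kb), Nr2f1 (10.6 kb), Bcl11a (10.5 kb), Zfp503 (10.3 kb) and Zfp516 (10.2 kb), the chromatin regulator genes Kdm6b (13.8 kb), Setd1b (11.7 kb) and Cbx8 (11.6 kb), and the signalling genes Pdgfra (11.6 kb), Irs2 (11.2 kb), Irs1 (10.9 kb) and Dusp6 (10.5 kb). A further 9 domains of that width held no annotated 5′ end of a protein-coding gene. Of these, 8 lay over other transcript starts of Tbx15, Trio, Igf2, Mecom, Lhx2, Tfap2a, Zmynd8 and Rarg. The ninth, 12 kb at chromosome 5:119795971 to 119807998, lay between genes 30.7 kb from Tbx5 and held the noncoding gene 1700021F13Rik.

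Among noncoding genes picked by name, Hottip, at the 5′ end of HoxA, had 9279 bp covered within 5 kb of its start (replicates 8352 and 9354 bp), Hoxa11os 9961 bp, Hand2os1 9883 bp and Hotair 7672 bp (replicates 4636 and 8056 bp). Each of these genes overlaps a wide domain at Hoxa, Hand2 or Hoxc genes, so its coverage cannot be told apart from that of its coding neighbours. Malat1 had 6755 bp, H19 5364 bp and Xist 959 bp (replicates 537 and 1033 bp), and Sox2ot and Dlx6os1, the latter beside Dlx6, had 0 bp in the replicated list (Dlx6os1 496 bp in replicate 2). Away from protein-coding starts by over 2.5 kb, 559 of 5385 lincRNA genes (10.4%, 95% Wilson interval 9.59 to 11.2) and 335 of 2083 antisense genes (16.1%, 14.6 to 17.7) had a peak within 1 kb of their start, against 7.21% of miRNA genes, 69 of 1381 snoRNA genes and 1.45% (1.23 to 1.71) of processed pseudogenes. Peak summits kept clear of CpG-rich starts: within 1 kb of the TSS of marked CpG-rich promoters, 7.98% of 12111 summits lay within 150 bp of the TSS, where an even spread puts 15%, with 60% further downstream and 32.0% further upstream. At CpG-poor promoters 22.8% of 2797 summits lay within 150 bp, 63.0% downstream and 14.2% upstream. CpG-rich here means the upper 5 deciles of CpG observed over expected, and CpG-poor the lower 5. Of the 3030 marked CpG-poor promoters, 1763 were in the fifth decile, next to the CpG-rich class. The highest peak of the replicated list was at Egr1, an immediate early gene, with a signal of 53.9. X-linked promoters fell below matched autosomal ones in both CpG classes, at 92.5% against 97.1% for CpG-rich and 27.8% against 33.4% for CpG-poor genes (two-sided permutation p = 0.0002 for each, the smallest possible), and no explanation was tested.

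Replicate 1 had narrower and weaker peaks than replicate 2. A different mix of cells in the embryo pools, as the whole cause, would leave promoters of genes used in all cells at equal signal. At 27 such promoter peaks, of housekeeping and cell cycle genes, the median log2 ratio of replicate 1 to replicate 2 was −1.04 (95% bootstrap interval −1.14 to −0.84), lower in replicate 1 at 27 of 27. Signal had already been seen lower at 97.1% of all 8542 unique pairs within 1 kb of a TSS, so this outcome was nearly given. It shows that the lower signal reached these promoters. With the normalization of signal unknown, it does not decide on cell mix. Lower enrichment or fewer reads in replicate 1 stay open, and the test tried on them decides nothing: of the 3419 replicate 2 peaks at a −log10 q of at least 5 with no counterpart, 100% were in the weaker part of such peaks, below the middle of their ranking by p-value, but the 13992 stronger ones lie among the 15084 strongest replicate 2 peaks, already seen to be all shared. With no read counts these cannot be told apart, and a difference in cell mix stays open and was not excluded.

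Limb mesenchyme genes were broader than CpG-matched lists by 4614 bp. Without the Hox genes the other 48 genes kept an excess of 4086 bp, matching on CpG density over the whole 10 kb window left 3505 bp, and matching on neighbouring TSSs in the window left 4683 bp (two-sided permutation p = 0.0002 in each, the smallest possible). With 39 of the 57 genes already seen to have over 5 kb covered, the outcome without the Hox genes was largely given. It shows only that the excess was not confined to the Hox clusters. CpG-dense sequence and neighbouring promoters are each argued against as the whole cause. Matching on CpG density over the window left 76.0% of the excess, and whether that density causes part of the breadth was not tested. A link between breadth and the use of these genes in the limb is a hypothesis that a single tissue cannot test. The random lists were not matched on kind of gene, such as regulators of development, so kind of gene was not tested as a cause either.

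Ectoderm, muscle, neural crest, brain and housekeeping genes together, 142 genes, had 1.20 more distal peaks per gene than territory-matched lists. The excess was 1.14 with lists also matched on the presence of a promoter peak, and 0.85 with peaks near any annotated transcript start left out. These lists were put together because each had passed, a choice that favours a large excess, so its size is not read as an estimate. Only what was left of it after each change is read. For the excess seen in these lists, a marked promoter and other annotated starts are each argued against as the whole cause. Leaving out those peaks lowered the mean of the lists from 2.08 to 1.43 and of the matched lists from 0.877 to 0.58 alike. The brain, muscle and neural crest calls ended with either replicate alone, and the ectoderm call with replicate 2 alone. Whether the pattern holds for these lists stays open.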
